A study of Nicotiana tabacum with 6 samples.

How the data were processed

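Total RNA from 3 stages of tobacco pollen development, with 2 biological replicates each, was measured on 6 one-colour Agilent arrays. Per the labels' protocols, anthers were mashed in 5% sucrose, the suspension was passed through gauze, and the cells were sedimented at 2000 g. RNA was extracted from 100 mg of this material and 66 ng of it was labelled with Cy3. Anther wall, tapetum and other sporophytic cells that pass gauze were therefore not excluded by the preparation. The labels call the replicates biological but do not say whether they came from separate plants or collections, so the p-values measure the spread between these samples.

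Each array's deposited file holds spot intensity from Agilent Feature Extraction version 11.0.1.1, per the file headers. It gives the background-subtracted intensity, the processed signal, the local background and the software's detection calls for each spot. The authors also deposited a series matrix of values on a linear scale. Each of its columns ranked the probes as that array's background-subtracted signal did (the lowest Spearman correlation was 0.99998). The column medians were 2.45 and 2.43 for microspores, 2.54 and 2.77 for early bicellular pollen, and 2.52 and 2.65 for late bicellular pollen. How those values were scaled and centred is not given in the sources used here. The matrix therefore served only as an alternative, with values under 1 set to 1.

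Control spots and spots called outliers by the software were left out, and spots of one probe were averaged, which left 43759 probes for 40144 gene identifiers. The main values were log2 of the processed signal minus the 75th percentile of the array's non-control probes, here called normalised log2 signal. A probe was counted as detected in a stage when both arrays called it well above background. Probes detected in at least 1 stage and with a value in every stage were tested. These were 24146 probes for 21624 genes. Gene names are the descriptions in the array files, which can be old. None of the 40425 identifiers matched the RefSeq table (0 matches), and 12.89% of the probes carried a description that names a product. One probe stood for each gene in lists and named genes, the one with the highest mean signal. Of 2166 genes with several tested probes, 8 had probes called in opposite directions between microspores and early bicellular pollen, 1 between early and late, and 6 between microspores and late.

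The test was limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend) on all 6 arrays with 1 mean per stage, which leaves 3 residual degrees of freedom. All stages share 1 estimate of the spread, although the replicates scattered unequally. Between the microspore arrays 8.17% of the tested probes differed more than 2-fold, against 1.64% in early and 2.18% in late bicellular pollen. P-values were adjusted by Benjamini-Hochberg over the tested probes of a comparison, with a threshold of 0.05. Counts are also given for probes that in addition changed at least 2-fold. Where a probe was not well above background on either array of the dimmer stage, the change is an approximate bound, given as at least N-fold. For it the probe's signal on each array of the dimmer stage was raised to the lowest signal among the probes well above background there, if it lay under that. Detection limits differ between probes, and an undetected probe can lie above this lowest signal. The least change a probe allows can therefore be smaller than the N given. Errors of log2 changes are standard errors (SE) of the fit, and those of stage levels are standard deviations (SD) over 2 arrays.

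Before the data were examined, 41 gene lists were fixed as word patterns for the descriptions, among them lists for other cells of the anther (tapetum, phenylpropanoid enzymes of the anther wall, photosynthesis, lignin and vascular tissue, defence). Matches that did not belong were removed after the matched descriptions were read, and the lists without this correction were run as an alternative. After that 39 lists had at least 3 tested genes. No probe matched the rapid alkalinization peptides, and none of the matches of the sperm and generative cell list held up, so the male germline has no list here. Lists were tested with camera at a preset correlation between genes of 0.01, adjusted over the lists of a comparison, beside camera with an estimated correlation and beside fry. The number of list members past the threshold is over all genes tested, and was also taken adjusted over the list alone.

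Named genes follow a rule set before the data were examined. In each comparison these are the 8 largest rises and 8 largest falls among genes with a named product that passed the threshold, changed at least 2-fold and had both arrays of one stage above both of the other, one per description. To these come up to 3 members of each list that passed, 2 in the list's direction and 1 against it, and at most 1 of a list that did not pass, to at most 30 genes with the clearest lists first. NTP303, LAT52, the core histones and the tapetal gene TA29 were fixed as checks of the stage labels. LAT52 was not found by name and the TA29 probe was too dim to be tested, so TA20, of the tapetum list, was taken in its place after the data were seen. A gene named outside the rule is said to be chosen after its values were seen.

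The arrays lay on 2 slides, each scanned as 1 batch. Slide 1 held replicate 1 of microspores and of early bicellular pollen, and slide 2 the other 4 arrays. Each comparison was therefore repeated with the slide as a block and within each slide that held both stages. Other alternatives were quantile normalization, scaling on the array median or on the spike-in probes (6 of the 10 on the array), normexp background correction with an offset of 50, the series matrix values, other filters on dim probes, a fit without the intensity trend, a fit on the compared stages alone, a test against a 2-fold change, the replicate number as a block, and leaving out each array. Scaling on the 75th percentile of probes detected on all 6 arrays was added after the data were seen.

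The procedure was tested on simulated data for 24105 probes at the real spread. Recovered or called here meant an adjusted p under 0.05 and an estimate of at least 2-fold. A true change of exactly 2-fold can miss that cutoff whatever the power. Of 100 probes changed 2-fold between microspores and early bicellular pollen 41 were recovered, and of 100 changed 4-fold 98. The numbers were 35 and 92 between early and late bicellular pollen, and 38 and 94 between microspores and late pollen. Of 23875 unchanged probes 3, 4 and 9 were called in these comparisons, which does not cover calls by adjusted p alone. A planted list of 30 genes shifted by 1 on the log2 scale passed camera in each of them, also with an estimated correlation (adjusted p = 0.0046, 0.0047 and 0.0047). Of the other lists camera called 1 between early and late bicellular pollen and 0 in the other comparisons, and 0, 0 and 0 with an estimated correlation. The simulated noise was independent for each probe and held no correlation between genes. It therefore cannot tell how the list tests behave where genes are correlated. Figures were drawn in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.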

Results

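The series followed the male gametophyte of tobacco (Nicotiana tabacum, cultivar Samsun) at 3 points of its development in the anther. Microspores, the cells with a single nucleus that are released after meiosis, came from flower buds of 15 to 16 mm (stage 1). Early bicellular pollen, which holds a vegetative and a generative cell after the asymmetric division, came from buds of 25 to 27 mm (stage 3), and late bicellular pollen, close to maturity, from buds of 46 to 49 mm (stage 5). Each stage had 2 biological replicates with 1 array each, and the number of arrays limits the precision of every value.

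Microspore arrays were dimmer than the others. The summed processed signal was 17607500 and 14982000 for microspores, 51842000 and 48495000 for early bicellular pollen, and 45995300 and 43388200 for late bicellular pollen. The spike-in probes differed little, with a mean log2 signal of 13.46 and 13.47, 13.24 and 13.33, and 13.34 and 13.25. Early bicellular pollen gave 2.94 times the microspore signal on slide 1 and 3.24 times on slide 2. The 10 brightest probes took 19.4% and 20.7% of the signal in microspores, 6.41% and 6.76% in early and 7.45% and 7.77% in late bicellular pollen. Without the 1000 brightest probes the ratio of early bicellular pollen to microspores was 3.58 on slide 1 and 3.88 on slide 2. The 75th percentile of the processed signal, from which changes are counted here, was 136 and 125 in microspores, 428 and 410 in early and 316 and 299 in late bicellular pollen, against a median local background between 19 and 25. A fold change is therefore a change relative to this percentile of the array.

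Replicates were close to each other and the stages lay apart. Across the tested probes, which are not independent of one another, Pearson's r between the replicate arrays was 0.978 for microspores, 0.993 for early and 0.993 for late bicellular pollen. Between stages it was 0.910 to 0.923 for early against late pollen, 0.657 to 0.670 for microspores against early pollen and 0.574 to 0.584 for microspores against late pollen. As checks of the stage labels, the pollen-specific gene NTP303 (X61146) had a normalised log2 signal of -0.10 ± 0.83 in microspores, 7.83 ± 0.01 in early and 8.60 ± 0.02 in late bicellular pollen (SD, n = 2). The tapetal gene TA20 (TC167356) ran the other way, from 3.62 ± 0.26 to -1.54 ± 0.22 and -2.07 ± 0.33 (SD, n = 2). Since the preparation did not exclude tapetum, the TA20 signal may come from carried-over cells, which was not tested.

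The first question of such a profile is how many genes each stage expresses. Probes well above background on both arrays numbered 16660 in microspores (38.1% of all probes), 22836 in early bicellular pollen (52.2%) and 19712 in late bicellular pollen (45.0%). All 3 stages shared 14408 probes, and early and late pollen shared a further 4939 that microspores lacked on at least 1 array, whereas microspores and late pollen alone shared 57. Early bicellular pollen had 2250 probes detected in no other stage, microspores 956 and late pollen 308. With the stricter condition that no array of another stage detected the probe, these numbers became 514, 669 and 140, so that the order of early pollen and microspores turned. Counted on at least 1 array, 22564 probes were detected in microspores, 25331 in early and 23416 in late pollen, and the software's positive-and-significant call gave 25440 in microspores on both arrays. Single arrays differed. Replicate 1 alone detected 16700 probes in microspores, 23120 in early and 19833 in late pollen, and replicate 2 alone 22524, 25047 and 23295. The SD of the negative controls was higher for replicate 1 (7.83, 5.86 and 7.42) than for replicate 2 (3.99, 4.50 and 3.98). A count over both arrays is therefore limited by the array that detected fewer probes.

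**Figure D1:**
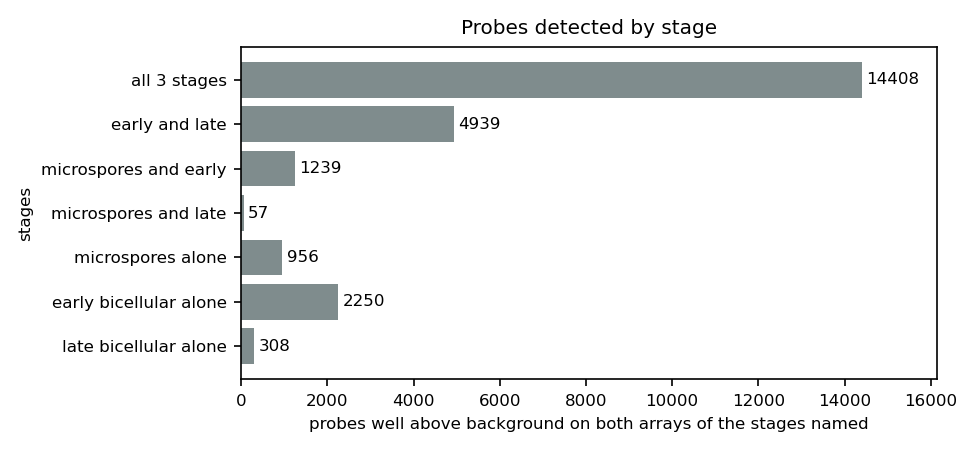
Bars give the number of probes well above background on both arrays of exactly the stages named on the vertical axis. The set shared by all 3 stages is the longest bar (14408 probes), followed by early and late bicellular pollen together (4939) and early bicellular pollen alone (2250), while 57 probes were shared by microspores and late pollen alone.

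From microspores to early bicellular pollen the steepest changes named here were those of single genes, which do not stand for their families (of 13 sugar transport genes 5 rose and 5 fell). Pectin methylesterase PPME1 (AY772945), which modifies wall pectin, rose by 8.70 ± 0.51 on the log2 scale (SE, adjusted p = 3.4e-06), and Sugar transport protein 10 (TC151520), a hexose carrier, by 8.36 ± 0.52 (adjusted p = 4.7e-06). Arabinogalactan peptide 13 (TC142048), a wall proteoglycan, rose by 9.11 ± 0.58 but was above background on only 1 of the 2 microspore arrays. Pollen coat-like protein (TC169125) rose at least 789-fold. Phosphoenolpyruvate carboxykinase (TC124511), an enzyme of gluconeogenesis, rose at least 305-fold and the vacuolar water channel bobTIP26-1 (TC153851) at least 288-fold. In the other direction Protein 108 precursor (TC137017) fell by 11.32 ± 0.13 (SE, adjusted p = 1.5e-08). Phosphoenolpyruvate carboxylase (TC143172), which fixes inorganic carbon into oxaloacetate, fell by 8.92 ± 0.14 and a hydroxyproline-rich glycoprotein of the wall (TC161698) fell at least 633-fold.

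Genes that were to become abundant later differed between the microspore replicates. Among 112 genes that rose by at least 6 on the log2 scale to a level of at least 2, 85 were brighter on microspore array 1 than on array 2, with a median difference of 1.05 (log2). For NTP303 the rise was 7.34 within slide 1 and 8.50 within slide 2, and for PPME1 7.78 and 9.62.

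Of the gene lists, 7 of 39 passed camera between microspores and early bicellular pollen, 5 higher and 2 lower, and 0 with an estimated correlation, where 2 lists had an unadjusted p under 0.05 (fry passed 35 lists). With median scaling and with normexp 14 lists passed, and 3 with the series matrix values. Pollen-specific genes (median 5.32, from 2.33 with normexp to 7.19 with spike-in scaling) did not pass in the values used here. They passed with median scaling (adjusted p = 1.4e-09), normexp (1.1e-06) and the percentile over probes detected on all arrays (0.040). Callose and cellulose synthases (median 1.95) passed in the same settings (0.0080, 0.011 and 0.027). Neither list passed with quantile normalization, spike-in scaling or the series matrix values. Cytosolic ribosomal protein genes rose: 149 of 176 rose and 13 fell, with a median log2 change of 0.86 (0.87 within slide 1, 0.91 within slide 2; camera adjusted p = 1.7e-12; adjusted p = 0.30 with an estimated correlation). Among them were a pair of 60s acidic ribosomal proteins, TC137217 (3.87 ± 0.07) and TC136097 (3.03 ± 0.07), while Ribosomal protein S4 (TC147863) fell by 1.95 ± 0.09. Genes of mitochondrial respiration rose in 41 of 51 cases and fell in 9, with a median of 2.15 (2.15 and 2.01 within the slides; adjusted p = 1.1e-06; adjusted p = 0.57 with an estimated correlation). A cytochrome c oxidase family gene (TC135383) rose by 4.16 ± 0.09 and Cytochrome b-c1 complex subunit 8 (TC143684) by 2.91 ± 0.06. Cytochrome c oxidase polypeptide Vc (TC156371) changed by -5.34 ± 0.16 and was above background on only 1 of the 2 early bicellular arrays.

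Proton pumps and ion transporters (17 of 22 rose, 4 fell, median 0.94), starch metabolism (15 of 23 rose, 4 fell, median 1.39, or 1.13 with genes at their bounds) and lipid and oil synthesis (15 of 21 rose, 5 fell, median 1.78) were also higher in early bicellular pollen. Their adjusted p was 0.027, 0.034 and 0.034, and adjusted p = 0.57 with an estimated correlation for each. Their medians were 1.29 and 0.95, 1.04 and 1.79, and 1.86 and 1.56 within slides 1 and 2. The inorganic pyrophosphatases X83729 and TC130320 rose by 3.19 ± 0.09 and 3.16 ± 0.09, and the potassium channel NKT1 (AB196790) fell by 2.20 ± 0.16. The levels of X83729 at the 3 stages (0.93, 4.12 and 4.10) were close to those of TC130320 (1.05, 4.22 and 4.20). Whether both identifiers stand for the same gene was not checked. Granule-bound starch synthase 1 (TC143810), the enzyme that makes amylose and a gene chosen after its values were seen, rose by 5.76 ± 0.08.

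Photosynthesis genes fell from microspores to early bicellular pollen, with 33 of 42 lower, 7 higher and a median of -2.32 (-2.48 and -2.14 within the slides; adjusted p = 8.8e-04; adjusted p = 0.57 with an estimated correlation). The Photosystem II 44 kDa protein (TC143855) fell by 3.36 ± 0.08 and the photosystem I assembly protein ycf3 (TC163864) by 2.14 ± 0.06, while ferredoxin-NADP oxidoreductase (AB004307) rose by 2.77 ± 0.08. Lists for other anther cells did not pass in these values. Their median was -3.70 for 3 tapetal genes (adjusted p = 0.45), -1.28 for 11 defence genes (0.30), -0.07 for 16 lignin and vascular genes (0.74) and -0.75 for 9 phenylpropanoid genes (0.73), whose mean was 0.21. Tapetal genes did pass as lower with median scaling (median -2.94, adjusted p = 0.038), spike-in scaling (-1.83, 0.014) and normexp (-2.98, 0.0022), but without the list corrections their median was 0.99 (0.97). Defence genes passed with spike-in scaling (adjusted p = 0.025), where their median of 0.58 lay below that of all probes (1.89), and in the values used here both lists had adjusted p = 0.70 with an estimated correlation. Mitotic cell cycle genes fell, 15 of 21 lower and 4 higher with a median of -1.20 (-1.15 and -1.26 within the slides; adjusted p = 0.027; adjusted p = 0.57 with an estimated correlation). With spike-in scaling, which moved the median of all probes to 1.89, that of the mitotic list turned to 0.66 but stayed below theirs, and the list still passed. Besides a cyclin B-like gene (AY776171, -5.81 ± 0.20), this list held homologs of CDC48 such as TC141620 (-2.48 ± 0.11), an ATPase that extracts proteins for degradation and acts outside mitosis too. Proton pumps and lipid synthesis did not pass with quantile normalization (adjusted p = 0.073 and 0.088). These lists and starch metabolism did not pass with spike-in scaling (0.15, 0.42 and 0.15) or the series matrix values (0.097, 0.12 and 0.097), and mitotic genes did not pass with the series matrix values (0.097) or without the list corrections (0.085).

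Over all probes, 19294 of 24146 were called between microspores and early bicellular pollen, and 13774 of these changed at least 2-fold (6799 higher and 6975 lower, for 12370 genes). Without a filter on dim probes 34709 were called (29216 at least 2-fold), among probes above background on all arrays 12517 (7632), and by a test against a 2-fold change 9663. The rise or fall reached at least 8-fold for 1278 and 1536 probes. Of the called probes 50.4% were higher, but 70.8% with median scaling, 90.0% with spike-in scaling, 42.5% with normexp and 43.6% with the percentile over probes detected on all arrays. Of those changed at least 2-fold 49.4% were higher, and in the same settings 75.2%, 91.0%, 43.2% and 40.8%. With the slide as a block 13823 probes were called at least 2-fold, 13745 of them shared with the 13774.

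**Figure D2:**
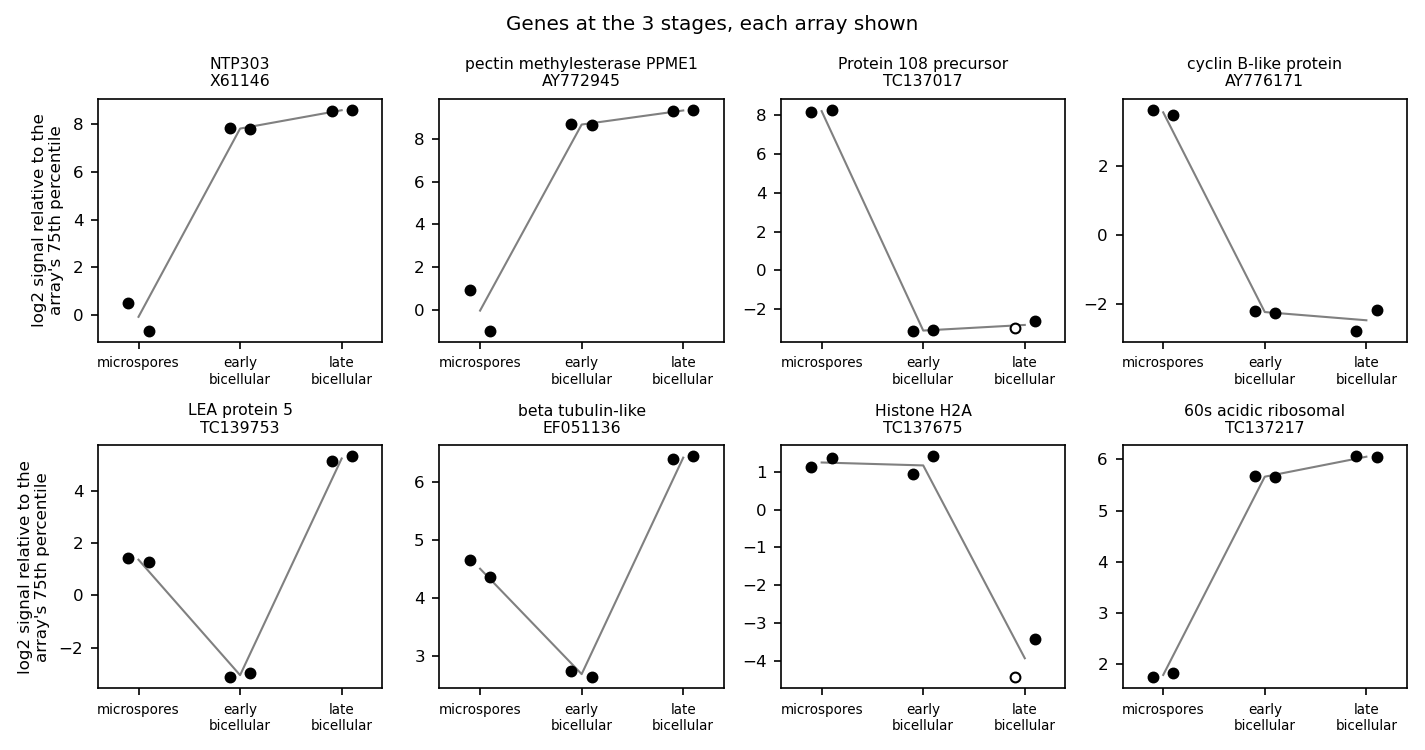
Points give the log2 signal relative to the array's 75th percentile (vertical axis) on each of the 2 arrays per stage (horizontal axis) for 8 named genes picked after their values were seen, filled where well above background, and lines join the stage means. NTP303 climbs from -0.10 to 7.83 and 8.60, Protein 108 precursor drops from 8.21 to -3.11 and -2.82, and LEA protein 5 falls to -3.05 in early bicellular pollen and reaches 5.24 in late pollen.

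From early to late bicellular pollen core histone and cytosolic ribosomal protein genes fell as lists (adjusted p = 0.32 and 0.13 with an estimated correlation), and the steepest rises named here were those of single genes. Late embryogenesis abundant protein 5 (TC139753), of a family linked to drying tissues, rose by 8.28 ± 0.11 (SE, adjusted p = 8.0e-08), and D-3-phosphoglycerate dehydrogenase (TC128209), an enzyme of serine synthesis, by 7.16 ± 0.20. An extensin-like wall protein (TC150449) rose by 6.35 ± 0.22. The sucrose transporter SUT3 (AF149981) rose by 6.21 ± 0.41 and was above background on 1 of the 2 early arrays. A pectin methylesterase precursor (TC128473) rose by 5.76 ± 0.22 and beta-carbonic anhydrase (TC122974) rose at least 44.3-fold. Histone H2A (TC137675) fell by 5.12 ± 0.33 and Histone H2B (TC147739) by 4.43 ± 0.26, each above background on 1 of the 2 late arrays. The rRNA-processing protein EBP2 homolog (TC128495) fell by 3.53 ± 0.10.

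Of the lists, 16 of 39 passed between early and late bicellular pollen, 11 higher and 5 lower, and 0 with an estimated correlation, where 2 had an unadjusted p under 0.05 (fry passed 34). Cytosolic ribosomal protein genes, higher in the step before, now fell in 154 of 176 cases (155 adjusted over the list alone) and rose in 4, with a median of -0.70 (-0.73 with the slide as a block and -0.71 within slide 2; adjusted p = 9.4e-23; adjusted p = 0.13 with an estimated correlation). Ribosomal protein L37-1 (TC142121) fell by 1.69 ± 0.06 and L13 (TC158910) by 1.43 ± 0.07, while TC137217 rose by 0.39 ± 0.07, which became -0.070 with spike-in scaling and -0.079 with the series matrix values. Core histone genes fell in 27 of 30 cases and rose in 3, with a median of -1.73 (-1.69 at bounds, -1.75 with the slide as a block, -1.84 within slide 2; adjusted p = 2.7e-10; adjusted p = 0.32 with an estimated correlation). Histone H3 (TC135658) fell by 2.74 ± 0.09, and another histone H3 (AB015760) rose by 0.39 ± 0.08, which became -0.067 with spike-in scaling and -0.21 with the series matrix values.

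RNA-binding protein genes fell in 30 of 52 cases and rose in 7, with a median of -0.56 (-0.55 with the slide as a block, -0.72 within slide 2). Heat shock and chaperone genes fell in 29 of 59 cases and rose in 8, with a median of -0.37 (-0.36 and -0.35). Both lists passed (adjusted p = 4.7e-05 and 0.0072; adjusted p = 0.32 with an estimated correlation for both). Fibrillarin (AB207972), a protein of rRNA modification in the nucleolus, fell by 2.88 ± 0.10. Of 12 auxin response genes 6 fell and 0 rose, with a median of -0.63 (-0.72 with the slide as a block, -0.71 within slide 2; adjusted p = 0.034; adjusted p = 0.32 with an estimated correlation).

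Among the rising lists, tubulin and kinesin genes rose in 15 of 21 cases and fell in 1 (median 0.77, 0.80 with the slide as a block, 0.85 within slide 2; adjusted p = 2.5e-04; adjusted p = 0.32 with an estimated correlation). A beta tubulin-like gene (EF051136) rose by 3.73 ± 0.10 and Alpha-tubulin 4 (TC134956) by 1.94 ± 0.09, whereas gamma tubulin (AJ278739) fell by 1.39 ± 0.17. Actin cytoskeleton genes rose in 14 of 21 cases and fell in 6 (median 0.69, 0.80 with the slide as a block, 0.77 within slide 2). Pectin enzymes rose in 8 of 13 cases and fell in 2 (median 1.35, 1.43 and 1.54 in the same settings). Pollen-specific genes rose in 5 of 10 cases (median 1.25, but 1.87 with the slide as a block and 1.34 within slide 2). Their adjusted p was 0.044, 0.034 and 0.025, and adjusted p = 0.32 with an estimated correlation for each. The pectin list no longer passed without late replicate 1 (adjusted p = 0.052). Genes of mitochondrial respiration rose in 32 of 51 cases and fell in 3 with a median of 0.37 (0.36 with the slide as a block, 0.42 within slide 2; adjusted p = 1.9e-04; adjusted p = 0.32 with an estimated correlation). That direction turned with spike-in scaling (-0.086), although the list stayed above the median of all probes (-0.39), and with normexp the median of 0.198 lay below theirs (0.22).

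Genes of lipid and oil synthesis rose in 12 of 21 cases (median 0.49, adjusted p = 0.0045), of vesicle exocytosis in 7 of 13 (0.55, 0.018) and of ethylene response in 8 of 10 (0.84, 6.2e-04), each with adjusted p = 0.32 with an estimated correlation. Late embryogenesis and dehydration genes rose in 5 of 10 cases (0.78, 0.034), lignin and vascular genes in 8 of 16 (0.52, 0.034) and aquaporins in 3 of 3 (1.49, 0.034), also with adjusted p = 0.32 with an estimated correlation. With the slide as a block these medians were 0.53, 0.57, 0.87, 0.88, 0.54 and 1.55, and within slide 2 they were 0.56, 0.61, 0.89, 0.84, 0.56 and 1.59. In the ethylene response list 2 of the genes encode small GTP-binding proteins and not transcription factors. The late embryogenesis list lost its call with the slide as a block (adjusted p = 0.054) and without microspore replicate 1 or 2 (0.13 for both). The aquaporins lost it without either microspore replicate (0.067 for both). Without the list corrections, which were made after the matches were read, pectin (0.14), actin (0.055), late embryogenesis (0.065) and lignin (0.21) did not pass. Calls of mitochondrial respiration (0.11), vesicle exocytosis (0.18) and auxin response (0.051) were lost with median scaling and also with normexp (0.68, 0.21 and 0.12). Spike-in scaling ended the calls of mitochondrial respiration (0.15) and vesicle exocytosis (0.072), quantile normalization those of auxin response (0.058) and pectin (0.062), and the series matrix values those of mitochondrial respiration (0.34), auxin response (0.055) and late embryogenesis (0.055).

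In total 13693 probes were called between early and late bicellular pollen, and 5969 changed at least 2-fold (2528 higher and 3441 lower, for 5365 genes), 261 and 250 of them at least 8-fold. A fit on the compared stages alone called 16760 (6109 at least 2-fold). Among probes above background on all arrays 2764 changed at least 2-fold, and a test against a 2-fold change called 2450. Of the called probes 50.1% were higher, against 2578 of 12882 with spike-in scaling, 39.7% with the series matrix values, 39.4% with the percentile over probes detected on all arrays and 57.3% with normexp. Of those changed at least 2-fold 42.4% were higher, against 16.7% with spike-in scaling and 31.8% with that percentile, and normexp gave 3047 such probes with 51.6% higher. With the slide as a block 6121 probes changed at least 2-fold, 5562 of them shared with the 5969.

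Between microspores and late bicellular pollen, the ends of the series, the largest rises included genes that had already risen in the first step, and pectate lyases, enzymes that cleave pectin. Pollen coat-like protein (TC169125) rose at least 1651-fold, and Arabinogalactan peptide 13 (TC142048) by 10.22 ± 0.58 with 1 of the 2 microspore arrays above background. PPME1 (AY772945) rose by 9.36 ± 0.51 and the pectate lyases X67159 and TC147768 by 9.02 ± 0.43 and 8.93 ± 0.38 (SE, adjusted p = 7.9e-07 and 4.8e-07). Protein 108 precursor (TC137017) fell by 11.03 ± 0.13, above background on 1 of the 2 late arrays, and an aldose 1-epimerase-like gene (TC147324) by 7.45 ± 0.12. A thionin-like gene (TA11747_4097), related to small defence peptides, fell by 6.83 ± 0.15. For the late-pollen genes the same difference between the microspore replicates applies, with a rise of PPME1 of 9.84 with the slide as a block and 10.30 within slide 2.

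Of the lists, 13 of 39 passed, 9 higher and 4 lower in late pollen, and 0 with an estimated correlation, where 1 had an unadjusted p under 0.05 (fry passed 34). Pollen-specific genes rose in 9 of 10 cases with a median of 8.27 (6.66 at bounds, 8.87 with the slide as a block, 9.08 within slide 2; adjusted p = 0.0053; adjusted p = 0.40 with an estimated correlation). Genes of mitochondrial respiration rose in 40 of 51 cases and fell in 8, with a median of 2.62 (2.61 with the slide as a block, 2.55 within slide 2; adjusted p = 8.9e-07; adjusted p = 0.40 with an estimated correlation), among them ATP synthase subunit d (TC125842, 3.13 ± 0.06). Lipid and oil synthesis genes rose in 16 of 21 cases and fell in 4 (median 2.43, 2.38 with the slide as a block, 2.37 within slide 2; adjusted p = 0.0053; adjusted p = 0.40 with an estimated correlation). Delta-12 fatty acid desaturase (TC131746) rose by 6.04 ± 0.09 and Digalactosyldiacylglycerol synthase 2 (TC134048), which makes a membrane galactolipid, by 4.62 ± 0.08, while a stearoyl-acyl carrier protein desaturase (TC131615) fell by 4.78 ± 0.16.

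Core histones fell in 24 of 30 cases and rose in 2 (median -2.21, -1.90 at bounds, -2.24 with the slide as a block, -2.21 within slide 2; adjusted p = 1.8e-05; adjusted p = 0.49 with an estimated correlation), with Histone H2B-like (TC134562) at -4.86 ± 0.11 and Histone H2B (TC148161) at 1.13 ± 0.06. Photosynthesis genes fell in 31 of 42 cases and rose in 7 (median -2.60, -2.09 at bounds, -2.64 with the slide as a block, -2.63 within slide 2; adjusted p = 0.0053; adjusted p = 0.42 with an estimated correlation). The other anther lists did not pass, with medians of -3.22 for tapetal genes (adjusted p = 0.65), -1.32 for defence genes (0.685), -1.28 for phenylpropanoid genes (0.53) and -0.16 for lignin and vascular genes (0.98), whose mean was 0.05. RNA-binding protein genes fell in 38 of 52 cases and rose in 10 (median -1.18, -1.21 with the slide as a block, -1.22 within slide 2; adjusted p = 8.1e-04; adjusted p = 0.42 with an estimated correlation), although spike-in scaling turned the median to 0.22 (all probes 1.31). RNA-binding gricine-rich protein-1 (TC133337) fell by 3.74 ± 0.07 and a poly(A)-binding protein (TC122936) rose by 2.04 ± 0.10. Mitotic genes fell in 16 of 21 cases and rose in 3 (median -1.25, -1.28 with the slide as a block, -1.40 within slide 2; adjusted p = 0.0091; adjusted p = 0.40 with an estimated correlation), turned to 0.16 by spike-in scaling. Both lists stayed below the median of all probes with that scaling and still passed.

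Proton pumps and ion transporters rose in 15 of 22 cases (median 1.35, adjusted p = 0.0091), starch metabolism genes in 15 of 23 (1.07, or 0.89 at bounds, 0.0095) and callose and cellulose synthases in 7 of 8 (2.09, 0.0095), each with adjusted p = 0.40 with an estimated correlation. Tubulin and kinesin genes rose in 15 of 21 cases (1.69, 0.013) and actin cytoskeleton genes in 16 of 21 (1.53, or 1.36 at bounds, 0.014), also with adjusted p = 0.40 with an estimated correlation. Ethylene response genes rose in 8 of 10 cases (1.54, adjusted p = 0.017; adjusted p = 0.42 with an estimated correlation). With the slide as a block these medians were 1.34, 1.25, 2.17, 1.73, 1.52 and 1.54, and within slide 2 they were 1.31, 1.41, 2.25, 1.77, 1.51 and 1.56. Ribosomal protein genes, up in the first step and down in the next, did not pass over the whole interval (median 0.14, 78 higher and 49 lower of 176, adjusted p = 0.25), but they passed as lower with quantile normalization, where the median turned to -0.37 (0.0022). They passed as higher with spike-in scaling (median 1.55, adjusted p = 5.6e-05) and the series matrix values (0.59, 0.026), so that no direction is given here (adjusted p = 0.60 with an estimated correlation in the values used here). The ethylene response list did not pass with median scaling (adjusted p = 0.14) or the series matrix values (0.068), and spike-in scaling ended the calls of lipid synthesis (0.10), actin (0.16), starch (0.053), callose (0.056), tubulin (0.058) and ethylene response (0.083).

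Across this widest interval 19846 probes were called, and 14928 changed at least 2-fold (7276 higher and 7652 lower, for 13386 genes), 2086 and 2346 of them at least 8-fold. Among probes above background on all arrays 12593 were called (8191 at least 2-fold), and by a test against a 2-fold change 11428. Of the called probes 48.3% were higher, but 68.5% with median scaling, 79.0% with spike-in scaling and 39.0% with the percentile over probes detected on all arrays. Of those changed at least 2-fold 48.7% were higher, against 70.6% and 80.9% with these and 37.7% with that percentile, and normexp gave 9571 such probes with 51.1% higher. With the slide as a block 14996 probes changed at least 2-fold, 14523 of them shared with the 14928.

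**Figure D3:**
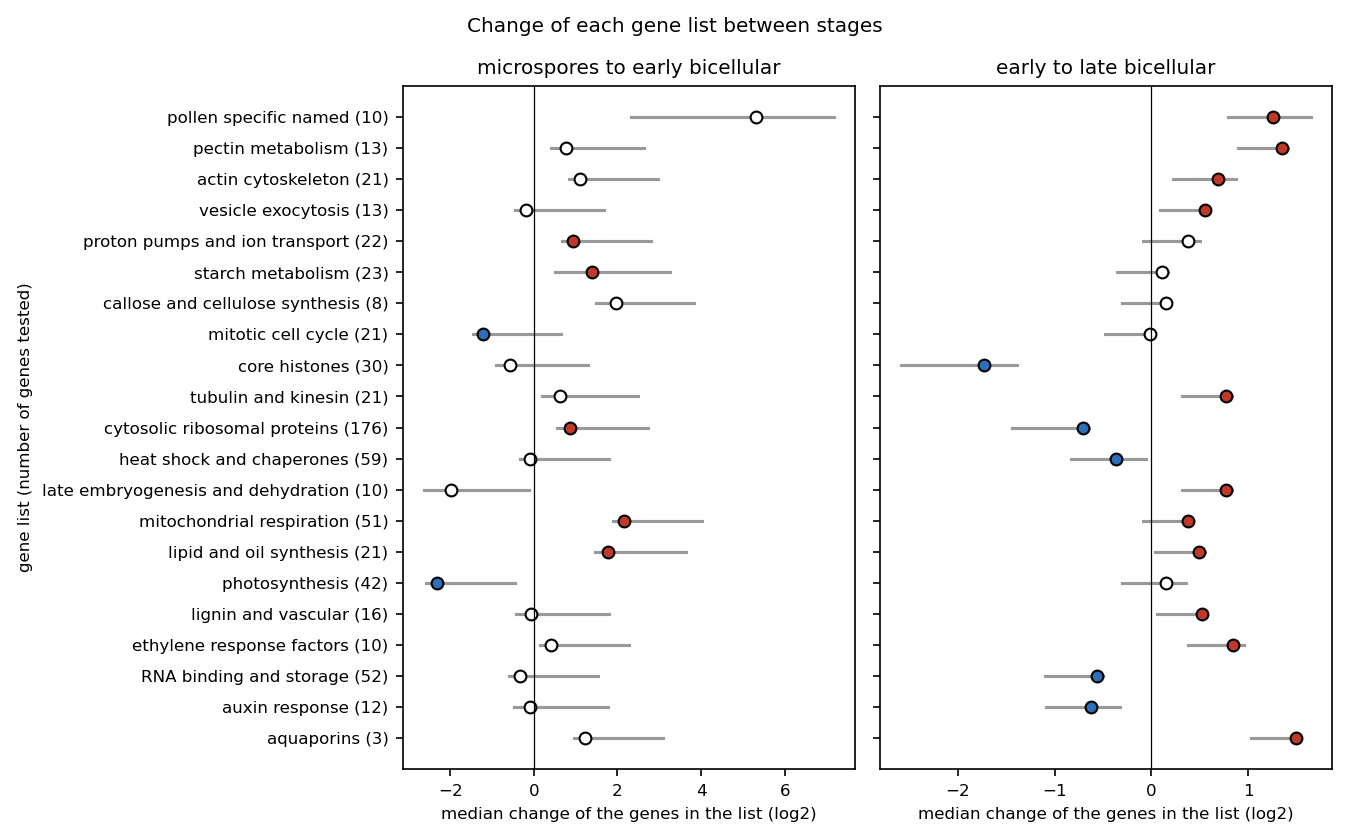
Points give the median log2 change (horizontal axis) of each gene list (vertical axis) from microspores to early and from early to late bicellular pollen, filled where the list passed camera at the preset correlation (0 passed with an estimated one), and lines span the medians under the 7 scalings. Ribosomal protein genes lie at 0.86 and then -0.70, histones at -1.73 between early and late pollen, and photosynthesis at -2.32 in the first step, while spike-in scaling, which moves all probes too (1.89 and -0.39), turns the mitotic list of the first step (0.66) and mitochondrial respiration between early and late pollen (-0.086).

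The median of all probes differed between scalings. In the values used above the median change of all probes was 0.02 from microspores to early pollen, 0.07 from early to late and -0.09 over the whole interval. The same medians were 1.89, -0.39 and 1.31 with spike-in scaling and 0.78, 0.13 and 0.71 with median scaling. The series matrix gave 0.41, -0.05 and 0.14 and quantile normalization 0.15, 0.02 and -0.03. With normexp they were -0.32, 0.22 and -0.22, and with the percentile over probes detected on all arrays -0.24, -0.08 and -0.50. Counts of list members adjusted over the list alone were equal to those over all genes for the 7 lists of the first step, and differed by at most 1 for the passing lists of the others. No passing list had a median and a mean of opposite sign.

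Changes of at least 2-fold in both steps were found for 3497 probes. Of these 1050 rose in both, 1177 fell in both, 749 rose and then fell, and 521 fell and then rose. LEA protein 5 (TC139753) was of the last kind, at 1.37 ± 0.12 in microspores, -3.05 ± 0.12 in early and 5.24 ± 0.11 in late pollen (SD, n = 2), as was D-3-phosphoglycerate dehydrogenase (TC128209) at 3.11 ± 0.34, -2.96 ± 0.37 and 4.20 ± 0.04. Histone H3 (TC135658) rose and then fell, from 1.69 ± 0.05 to 4.27 ± 0.15 and 1.54 ± 0.02. Independent lists of the same sizes would share 3405 probes, 712 rising in both, 994 falling in both, 969 rising then falling and 730 falling then rising. Simulated stages with no change shared 0 (20 simulations). Without any change hardly a probe is called in either step, so this 0 sets no chance level for the overlap of the real lists. Both steps use the same 2 early bicellular arrays, of which a split would leave 1 to each step. In the simulation this sharing alone drove the steps in opposite directions (correlation -0.50). The classes above independent lists were those with the same direction in both steps (1050 against 712 and 1177 against 994). These values argue against sharing as the source of that excess. The correlation of the steps across probes was 0.07 against -0.50 simulated with no change, with a covariance of 0.16 against -0.03, a difference of 0.19. The count of 3497 was 5564 with spike-in scaling, 5544 with the series matrix, 1491 with normexp and 1430 among probes above background on all arrays. The classes by direction are given in the values used here alone and depend on the scaling. With spike-in scaling 91.0% of the probes changed at least 2-fold rose in the first step, and 16.7% from early to late.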

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

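Scaling on the percentile of probes detected on all arrays, lists without the corrections, the slide block for lists and detection on a stage's other array were chosen after the data were seen. Unless a value below says why, the cause of a change was not tested. Without a filter on dim probes, 34709 probes were called from microspores to early pollen (29216 at least 2-fold). With probes above background on all 6 arrays, where fewer probes are tested, 12517 (7632) were called in that step. The count was 2764 at least 2-fold from early to late, 12593 (8191) from microspores to late, and 1430 in both steps. A test against a 2-fold change, a stricter question, called 9663, 2450 and 11428. Normexp gave 3047 probes changed at least 2-fold from early to late, 9571 from microspores to late, and 1491 in both steps, against 5564 with spike-in scaling and 5544 with the series matrix. Leaving out each array in turn, where the lone array is assumed to vary like the other groups, gave 17205 to 19972 calls in the first step, 10037 to 16660 in the next, 18012 to 20529 over both, and 2904 to 3540 in both steps. The labels do not say whether the replicate numbers mark a shared batch, and they were treated as names (correlations of same-numbered deviations 0.12, 0.06 and 0.10). With the replicate number as a block 19355, 13912 and 19948 probes were called, and of the list calls it changed 1, pectin over the whole interval (adjusted p = 0.041). Lists passing in the first step were 14 with median scaling, 14 with normexp and 3 with the matrix. With an estimated correlation 0, 0 and 0 passed in the 3 comparisons, with fry 35, 34 and 34. Spike-in scaling (all probes 1.89, -0.39 and 1.31) turned mitotic genes to 0.66 (first step) and 0.16 (whole interval), mitochondrial respiration to -0.086 (early to late), RNA-binding genes to 0.22 (whole interval), and from early to late pollen TC137217 to -0.070 and AB015760 to -0.067. The matrix turned these genes to -0.079 and -0.21. Quantile normalization put ribosomal protein genes at -0.37 over the whole interval. Fry's direction was opposite to the list median for ROP signalling (-0.23 in the first step, -1.08 over the whole interval), sugar transport (-0.077, -1.91), receptor-like kinases (-0.42, -0.61), WRKY (0.46, first step), starch (0.11) and beta-1,3-glucanase (0.41) from early to late, and calcium signalling (-0.082, whole interval). Of the 36 list calls 4 were lost with median scaling, 4 with quantile normalization, 3 with normexp, 8 with the matrix, 10 with spike-in scaling besides the 4 turned, and 5 without the list corrections. With the slide as a block the pollen-specific and callose lists newly passed in the first step (adjusted p = 0.047 each) and pectin over the whole interval (0.037). The software's positive-and-significant call gave 25440 probes in microspores. Replicate r was 0.992 with normexp, 0.989 with probes above background on all arrays and 0.965 with no filter for microspores, and 0.984 with no filter for early pollen. Probes near the local background (19 to 25) limit microspores most, whose 75th percentile was 136 and 125.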

Other observations

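The trace test over genes above background and the tests of array scaling were chosen after the result was seen, and the remaining tests before.

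Genes with the same description tended to move together. Among descriptions shared by several genes changed at least 2-fold, 50 of 262 held both directions from microspores to early pollen, against a mean of 153 (128 to 176) in 1000 shuffles of the directions. From early to late pollen it was 8 of 93 against 50.7 (38 to 64), and over the whole interval 57 of 288 against 170 (142 to 192). Array designs built from expressed tags can hold several sequences of one gene, and this count does not separate those from gene families.

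Single members of the transcription factor lists moved far in the first step. Of 12 bZIP factors 9 were lower and 2 higher, with a median of -1.74 (adjusted p = 0.099), but this list passed as lower than other genes with median scaling (-0.99, adjusted p = 0.032) and with spike-in scaling (0.0044), where its median turned to 0.12 (all probes 1.89). With an estimated correlation it did not pass in the values used here (adjusted p = 0.70). The members named here were chosen after their values were seen. BZI-4 (TC161426) rose by 4.15 ± 0.09 (SE) and again by 1.54 ± 0.09 from early to late pollen, whereas BZI-2 (TC142098) fell by 4.87 ± 0.16 in the first step and RSG (TC128752) by 4.71 ± 0.23. Arabinogalactan and extensin genes were mostly lower, 7 of 10 against 1 higher (median -2.44, adjusted p = 0.16), the higher one being the Arabinogalactan peptide 13 gene (TC142048, 9.11 ± 0.58). That list passed as lower with median scaling (-1.68, adjusted p = 0.021), spike-in scaling (-0.57, 4.1e-04) and normexp (-1.73, 0.010), and had adjusted p = 0.57 with an estimated correlation in the values used here. Core histones were split in the first step, with 10 of 30 higher and 16 lower (median -0.56, adjusted p = 0.30), a median that turned with median scaling (0.19) and spike-in scaling (1.30) but stayed below that of all probes there (0.78 and 1.89), and lay above it with normexp (-0.21 against -0.32). Of 4 NAC factors 3 fell from early to late pollen (median -1.11, adjusted p = 0.063).

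Late-pollen genes were brighter on microspore array 1 than on array 2 (median difference 1.05 over 112 genes). Uneven background of dim probes is argued against, since random lists of the same signal gave medians between -0.08 and 0.19 (percentile 100 of 10000 lists). A trace of later pollen or its RNA, in the sample or on the array, would add one share of the early bicellular signal to every gene. Over all 112 genes 39.3% lay within 2-fold of the median share, below the 50% set beforehand as evidence against it. That bound was wrong because only 18 genes were above background on both microspore arrays. Over those 94.4% lay within 2-fold (median share 0.341%), and 88.9% when the share was taken of the late bicellular signal (median share 0.192%). These genes were taken by their microspore signal after the first result, and the least rise of 6 on the log2 scale caps their share. A narrow spread of shares is thus partly built in, so these values cannot decide and a trace stays open. A trace in the sample was not separated from leakage between arrays of a slide, and replicate 1 being further along in development stays open too, since the 81 genes with the strongest falls were at percentile 50.79 of random lists and this does not exclude an early start of late genes alone.

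Photosynthesis genes were lower after the microspore stage (median -2.32), and array scaling is argued against for the fall relative to other genes. Of the scalings that can change it, normexp left the list nearest to the median of all probes, at -1.31 (bootstrap range -1.50 to -0.94). The bootstrap resampled the genes of a list and not the arrays, so its range holds no spread between replicates. Whether the level itself fell stays open, since the spike-in probes, with all probes at 1.89, put the list median at -0.457 with a bootstrap range of -0.92 to 0.30. Carry-over of green anther tissue stays open too: the list's difference between the microspore replicates was 0.11, at percentile 92.16 of random lists, and equal carry-over in both would not show. Of the other anther lists, the 9 phenylpropanoid genes lay outside the range of random lists (0.31 against -0.27 to 0.25, percentile 99.15). The tapetal, lignin and vascular, and defence lists lay inside (percentiles 90.98, 73.2 and 25.26). The 3 tapetal genes passed as lower with 3 of the 7 scalings (adjusted p = 0.0022 to 0.038, and 0.70 with an estimated correlation in the values used here). The Rubisco large chain (TC122913) and the photosystem II P680 protein (TC126534), chosen after their values were seen, fell by 1.54 ± 0.09 and 2.94 ± 0.09 (SE), and 38 of 42 list genes were above background on both microspore arrays, 30 on both early and 26 on both late arrays. A change of plastids with the stage itself was not tested.

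Ribosomal protein genes rose into early bicellular pollen and fell into late pollen. A brightness-dependent bias between arrays is argued against as the whole cause in both steps, by random lists matched on signal (percentile 99.56 for the rise and 0 for the fall). Those lists rose as well in the first step, with medians of 0.34 to 0.79 against 0.86, so that much of the rise was shared with equally bright genes, and in the next step they gave -0.05 to 0.26 against -0.70. Array scaling is argued against as well, since the scaling nearest to no change gave a median of 0.558 for the rise and -0.650 for the fall. Both medians lay outside 0 by more than the bootstrap spread over the list's genes, which leaves out the spread between arrays. Nearest relative to all probes were 0.412 and -0.775. A candidate explanation is a change of ribosome synthesis with the stage, a hypothesis that was not tested. The pattern itself was found and tested on the same arrays, and camera with an estimated correlation did not call the list in either step (adjusted p = 0.30 and 0.13).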
